A study of Mus musculus with 12 samples.

How the data were processed

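The series profiled miRNAs with a 1-colour array while mouse embryonic stem cells (mESC) of a 129/SVEV line were differentiated towards endoderm. Per the labels' protocols, cells were grown without feeders in N2B27 medium with LIF and inhibitors of MEK and GSK3. They were then moved to a chemically defined basal medium (CDM) for 2 days, and Activin A, Noggin and the GSK3 inhibitor CHIR99021 were added for the next 4 days. Total RNA was taken on Days 0, 2, 3, 4, 5 and 6 in each of 2 independent experiments, called sets here, which gives 12 arrays in 6 groups of 2. No culture without induction was analysed here at Days 3 to 6, so the effect of the inducers and the effect of time cannot be told apart.

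RNA was labelled with Cy3, and the arrays were read with Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. The array holds 4415 probes for 1881 mouse miRNAs on 56430 spots, with positions on the mm9 assembly in the file headers. Per the file headers, the deposited intensity values are spot brightness on a linear scale, with the spatial background already subtracted by the scanner software and no scaling between arrays. The authors' value table holds log2 values. Set against the scanner files, each of its columns matched log2 of that array's total gene signal within 5.57e-05, with miRNAs that were not detected at 0.1 before the log, which gives column medians of -3.32. It is neither scaled between arrays nor centred, and has no ratio whose direction could be unclear.

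Control spots and spots marked as outliers were left out of all fits (1125 to 1978 spots per array), and no spot was saturated. Spots of a probe were averaged. Each array was divided by its 75th percentile over the 279 probes well above background on all 12 arrays, which lay between 111 and 181 before scaling. Values were then raised to a floor of 10.4, the median over arrays of the 5th percentile of probes well above background, and log2 was taken, so that the floor is 3.38 on the log2 scale. The probe with the highest mean over the 12 arrays stood for its miRNA. Between 216 and 288 miRNAs per array were well above background. The number of arrays limits the precision, and 126 of the tested miRNAs lay at the floor on 6 or more arrays.

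miRNAs well above background on both arrays of at least 1 group were tested, which gave 337, of which 157 were well above background on all 12 arrays. Group means were fitted over all arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 6 residual and 0.942 prior degrees of freedom. All adjusted p-values are Benjamini-Hochberg values from this limma fit over the 337 miRNAs, with a threshold of 0.05, unless a list test is named. Changes are given as log2 differences ± standard error of the fit, and levels as mean log2 signal ± SD with n = 2. Groups with both arrays at the floor show no spread, which lowers the standard errors and p-values of such miRNAs. Where a miRNA was not well above background on any array of the dimmer group, or lay at the floor on any of them, the fold is a lower bound ("at least"), taken from the mean of the brighter group against the floor or the dim probe's own value where that is higher. Levels of different miRNAs are not compared. Among calls with a further probe above background, 1 call (Day 3 vs Day 2) had a further probe moving the other way by more than 0.3 log2.

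The 15 miRNA lists, the comparisons, the alternatives and the rule for named miRNAs were set before the data were examined. For Day 2 vs Day 0 and Day 6 vs Day 2 the rule names the 10 largest rises and the 10 largest falls among calls whose arrays do not overlap. For Day 3 vs Day 2 and Day 6 vs Day 0 it names 5 and 5, and for the test of any change the 5 with the smallest p. The scaling, the floor and the filter were fixed with it. It adds up to 4 members of each list with the smallest adjusted p, and a fixed set of known markers. The 11 lists with at least 3 tested members were tested with camera (preset correlation 0.01, adjusted over the 11 lists). camera with an estimated correlation and the fry rotation test were alternatives.

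Per the labels, equal set numbers come from the same experiment, so the numbers pair the samples. Differences between the sets correlated across miRNAs, which are not independent replicates, by 0.515 to 0.785 among Days 3 to 6, by 0.281 between Days 0 and 2, and by -0.277 to 0.308 between these and the later days. The arrays lie on 2 slides. The first holds all of Set 1 and Days 0 and 2 of Set 2 (8 arrays), and the second holds Days 3 to 6 of Set 2 (4 arrays). The set number and the slide were each tried as a block, and the first slide was also fitted alone. On the first slide Days 3 to 6 have 1 array each, so in the fit of that slide alone their changes are judged by the spread of Days 0 and 2. Such results are not a replicated check of Days 3 to 6. The second slide holds 1 array per group and gives no test by itself. With another scaling or signal the changes of the 157 miRNAs well above background on all arrays moved by a median of -0.52 to 0.59 log2, so that directions are relative to the scaling.

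The other alternatives were the percentile over all probes, quantile normalization, normexp background correction with an offset of 50, the total gene signal, the mean of all probes, the authors' value table, no filter, only miRNAs above background on all arrays, a floor 4 times higher, a variance trend, and leaving out each array. Alternatives chosen after seeing the data were the first slide alone, scaling by 4 kinds of control spots (hur_1, hur_2, hur_4 and hur_6, whose target is not given in the sources used here), the percentile over 141 probes with at most 60% GC, a linear GC correction with the replicate block, and a fit without miRNAs that have the same value on every array. There were 5 such flat miRNAs among the 337 tested, 1535 without the filter and 179 with the higher floor. In the last 2 cases they were left out of the fit and counted as unchanged, because rounding error over a spread of 0 otherwise passes the test. In the GC correction, values at the floor were kept there.

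The fit was tested on simulated data made from the 337 miRNAs with 50 of them changed at Day 6 by each of 4 sizes. For Day 6 vs Day 2 it recovered 76% of changes of 0.5 log2, 96% of changes of 1 and 100% of changes of 2 and of 3, with 3 false calls among 137 unchanged miRNAs. The simulated noise was independent between miRNAs and arrays and held no floor and no slide or set effect. These rates therefore do not cover such effects in the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene annotation of another assembly was not used here.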

Results

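The data are 12 miRNA arrays that follow mouse embryonic stem cells through 2 days in basal medium and 4 days of endoderm induction with Activin A, Noggin and CHIR99021. Each of the 6 time points has 2 arrays, 1 from each of 2 independent experiments. Between 293 and 372 miRNAs per array were detected by the scanner software, and replicate arrays correlated across the 337 tested miRNAs by 0.988 to 0.995. The first principal component held 47.3% of the variance and ran from Days 0 and 2 to Day 6. The second held 27.4% and set Day 0 apart from Day 3. Of the 337 miRNAs, 260 changed over the 6 days.

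The first comparison asks what changed as the stem cells left LIF and the inhibitors for 2 days in basal medium. The miR-302 cluster, which includes miR-367, marks primed pluripotent cells. It rose in all 6 tested members. miR-302a-3p went from 4.07 ± 0.45 to 7.91 ± 0.17 (n = 2 each), a log2 change of 3.83 ± 0.33 (adjusted p = 5.6e-05). miR-302b-3p rose by 3.54 ± 0.32, miR-302d-3p by 3.53 ± 0.29, and miR-367-3p by 3.39 ± 0.36, and miR-302c-3p was at least 4.51-fold higher. Members of the let-7 family, which is abundant in differentiated cells, fell below the background. let-7f-5p was at least 4.59-fold lower (adjusted p = 2.03e-05), let-7a-5p at least 3.71-fold, let-7g-5p at least 3.41-fold and let-7d-5p at least 1.58-fold. The fifth tested member, let-7e-5p, was not well above background on either day.

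In total 153 of 337 miRNAs changed between Day 0 and Day 2, with 70 higher and 83 lower at Day 2. The miR-290 cluster (miR-290 to miR-295), the main miRNA cluster of naive mouse stem cells, fell in 10 of its 14 tested members, but in 2 with the percentile over all probes, in 5 with quantile normalization, and in 6 with no filter, without Day 0 replicate 1 or without Day 2 replicate 1. miR-295-3p went from 10.90 ± 0.04 to 10.16 ± 0.18 (log2 change -0.74 ± 0.15, adjusted p = 0.00502) and miR-290a-5p fell by 0.76. miR-294-3p fell by 0.62 ± 0.20 (adjusted p = 0.0417). The polycistronic miR-17-92 family, linked to proliferation, rose in 12 of 17 members and fell in 4 (1 with the percentile over all probes, 2 on the first slide alone). miR-19a-3p rose by 1.54 ± 0.10, miR-20b-5p by 1.52 ± 0.10, and miR-19b-3p by 1.28 ± 0.08, and miR-18b-5p was at least 3.26-fold higher. The members placed at a single site split by locus. On chromosome 14 (115442951 to 115443462, mm9) 4 of 5 rose, and on chromosome X (50094923 to 50095579) 5 of 5 rose. On chromosome 5 (138606605 to 138607037) 4 of 4 fell.

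miRNAs of the imprinted Dlk1-Dio3 region on chromosome 12, where maternally expressed miRNAs are clustered, rose in 28 of 36 members at Day 2, and none fell (adjusted over the list alone, 29 higher and 1 lower; all other lists but that of miR-99, miR-100 and miR-125 had the same counts both ways). The count that rose was 9 with the floor 4 times higher, 15 in the authors' value table, 17 when scaled on probes of low GC content, and 7 of the 10 members above background on all arrays. With low-GC scaling 2 fell, and 1 fell with the percentile over all probes, the variance trend, the replicate block with or without GC correction, or without either array of Day 0. miR-541-5p rose by 1.67 ± 0.11, miR-370-3p by 1.58 ± 0.12, miR-154-3p by 1.39 ± 0.05 and miR-337-3p by 1.07 ± 0.03. miR-341-3p was at least 3.11-fold higher and miR-381-3p at least 2.53-fold. The 28 members with a single site lie between 110828676 and 110986124. With camera, the lists called higher were Dlk1-Dio3 (adjusted p = 1.51e-13), miR-302 (adjusted p = 0.00118) and miR-17-92 (adjusted p = 0.00448). Those called lower were miR-290 and let-7 (adjusted p = 0.00448 each), and the miR-290 call ended with quantile normalization (adjusted p = 0.0643). Only Dlk1-Dio3 was called with an estimated correlation (adjusted p = 0.0405). The values were an adjusted p = 0.402 for miR-302 and let-7, and an adjusted p = 0.405 for miR-17-92 and miR-290, each with an estimated correlation.

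The largest fall at Day 2 was that of miR-211-5p, which was at least 9.05-fold lower (6.57 at Day 0, and at or near the floor at Day 2, adjusted p = 5.44e-11). miR-26a-5p fell by 2.36 ± 0.12, miR-24-3p by 2.07 ± 0.16, miR-301a-3p by 1.96 ± 0.08 and miR-107-3p by 1.75 ± 0.08. miR-181d-5p was at least 3.89-fold lower and miR-324-5p at least 3.45-fold lower. miR-34a-5p, a target of p53, fell by 0.97 ± 0.11, and miR-21a-5p rose by 0.88 ± 0.09. miR-148a-3p, in the list of endoderm and gut miRNAs, fell by 1.01 ± 0.10. miR-196a-5p, which lies in the Hox clusters, was at least 2.27-fold lower. miR-200c-3p (log2 change 0.32 ± 0.14, adjusted p = 0.107) and miR-124-3p (adjusted p = 0.236), which was not well above background at Day 2, did not pass the test. In the miR-200 list 2 of 5 members fell (1 with the total gene signal, and 0 with the percentile over all probes, normexp, the authors' value table, the floor 4 times higher or hur control spots), its median was 0.12, and camera's direction was lower (adjusted p = 0.605). The median turned to -0.22 when scaled on probes of low GC content. In the miR-99, miR-100 and miR-125 list 2 of 5 members fell, and 1 when adjusted over the list alone or without either array of Day 0, 2, 3 or 4. None fell with the floor 4 times higher, and 3 fell with the total gene signal or in the authors' value table.

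All 153 calls had the same sign in both sets, which selection on the mean of the same Day 0 and Day 2 arrays makes likely by itself. These arrays share the first slide, where 143 miRNAs were called alone, and 177 with slide as a block. The share of calls that were higher was 45.8% here and 28.1% to 62.6% over the other scalings. miR-294-3p did not pass without either array of Day 0 (log2 change -0.65 and -0.58) or of Day 2 (-0.53 and -0.70), without either array of Day 5 (adjusted p = 0.0509), or with the percentile over all probes (-0.54), quantile normalization (0), no filter (adjusted p = 0.214), the floor 4 times higher (adjusted p = 0.0781) or scaling by hur control spots (-0.51), and miR-295-3p did not pass with the percentile over all probes (-0.66) or quantile normalization (-0.27). The higher floor also ended the calls of miR-302c-3p (0.42, adjusted p = 0.727), miR-154-3p (0.04), and, with a change of 0 each, miR-18b-5p, miR-341-3p, miR-370-3p, miR-381-3p, miR-337-3p, let-7a-5p, let-7d-5p, let-7g-5p, miR-181d-5p, miR-324-5p, miR-148a-3p and miR-196a-5p. let-7d-5p (adjusted p = 0.053) and miR-148a-3p (-0.14) did not pass with normexp, nor miR-337-3p in the authors' value table (0.87). miR-200c-3p passed with the mean of all probes (0.33) and without either array of Day 3 (adjusted p = 0.0181), and miR-124-3p with the total gene signal (-0.88), in the authors' value table (-4.46) and without Day 0 replicate 1 (-0.14).

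**Figure D1:**
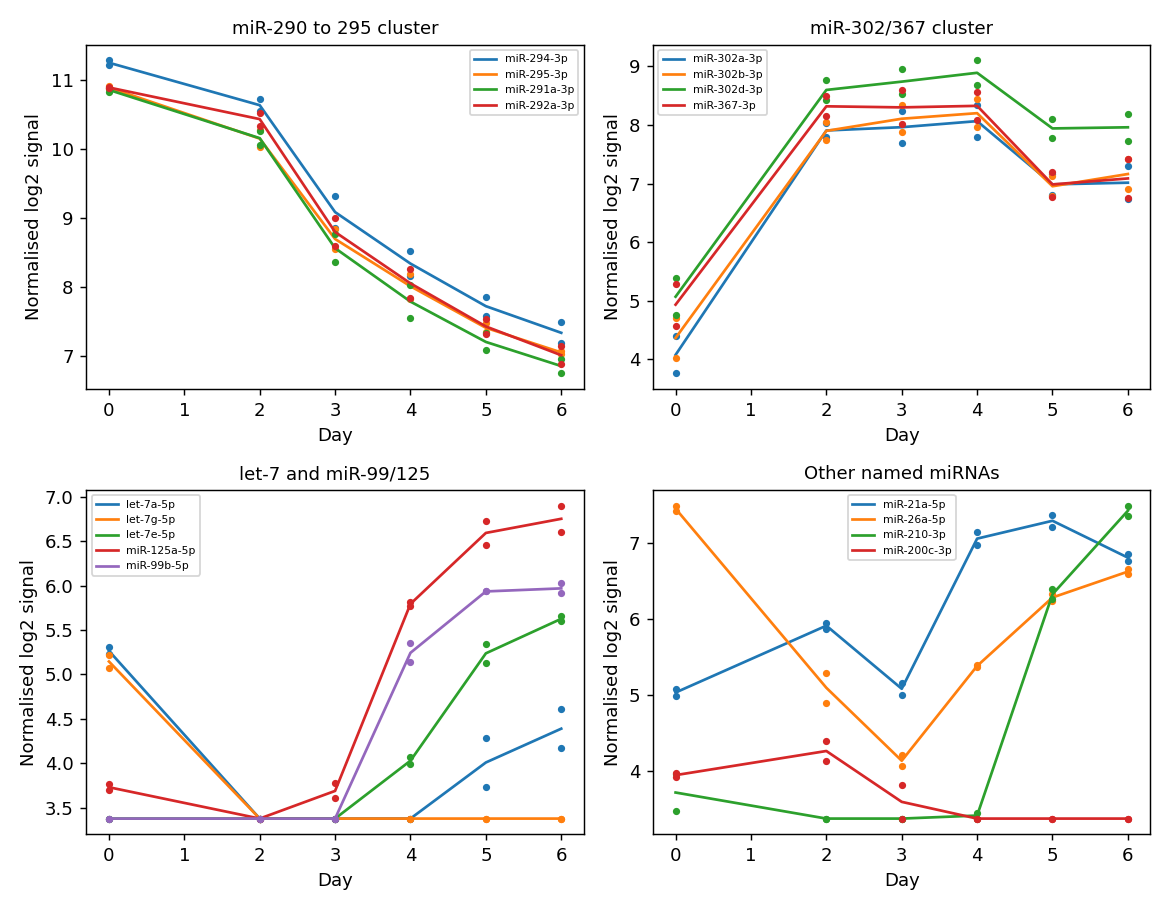
Normalised log2 signal (vertical axis) against day of differentiation (horizontal axis) for 4 groups of miRNAs. Points are single arrays (2 per day), lines join the group means, and 3.38 is the floor. miR-294-3p falls from 11.26 to 7.34, while miR-302a-3p steps from 4.07 to 7.91 at Day 2.

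The second comparison asks what followed the first day of induction. Between Day 2 and Day 3 the miR-290 cluster fell in 11 of 14 members (each list count at Day 3 was the same when adjusted over the list alone), and Dlk1-Dio3 miRNAs fell in 33 of 36 and rose in 1. No miR-290 member rose, but 2 did with the total gene signal, with hur control spots or in the authors' value table and 1 with quantile normalization, and 9 to 14 of the 14 fell over the alternatives that tested all of them. Of the Dlk1-Dio3 members 7 fell with the floor 4 times higher, 16 in the authors' value table, and 8 of the 10 above background on all arrays, while 3 rose with hur control spots and 2 without Day 3 replicate 1. miR-290a-3p was at least 4.75-fold lower (adjusted p = 5.18e-07). miR-294-3p fell by 1.55 ± 0.20, miR-295-3p by 1.46 ± 0.15 and miR-294-5p by 1.69 ± 0.06. No member of the miR-302 cluster was called, though 3 were higher with the replicate block and GC correction, 2 with hur control spots or in the authors' value table and 1 with slide as a block, and 1 was lower with normexp, the total gene signal or without Day 2 replicate 2. Its median was 0.10 and turned to -0.07 with the total gene signal. miR-302a-3p differed by 0.06 ± 0.33 and miR-367-3p by -0.02 ± 0.36.

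Of 337 miRNAs, 163 changed, 76 higher and 87 lower at Day 3. In the Dlk1-Dio3 region miR-154-3p was at least 4.11-fold lower, miR-411-3p at least 3.25-fold and miR-337-3p at least 2.91-fold, and miR-376b-3p fell by 1.74 ± 0.09 and miR-341-3p by 1.51 ± 0.04. miR-142a-3p, a miRNA of blood cells, was at least 4.83-fold lower. In the authors' value table miR-142a-3p (-2.33, adjusted p = 0.118), miR-411-3p (-1.12, adjusted p = 0.369) and miR-337-3p (-0.99) did not pass. With the floor 4 times higher miR-142a-3p (-0.27, adjusted p = 0.505), miR-154-3p and miR-294-5p (-0.04 each) did not, nor did miR-411-3p, miR-337-3p, miR-341-3p and the 3 miRNAs of the miR-200 family named next, with a change of 0 each. The epithelial miR-200 family fell in 3 of 5 members (5 with normexp), with miR-200b-3p at least 1.75-fold, miR-141-3p at least 1.66-fold and miR-200c-3p at least 1.59-fold lower. In this order they did not pass with the percentile over all probes (-0.64, -0.57 and -0.51), with hur control spots (-0.34, -0.31 and -0.19) or in the authors' value table (-0.25, -0.24 and -0.19). miR-141-3p and miR-200c-3p also did not pass on the first slide alone (-0.55 and -0.45) or when scaled on probes of low GC content (-0.41 and -0.32), nor miR-200b-3p and miR-141-3p with the replicate block and GC correction (-0.49 and -0.42). miR-17-92 members fell in 11 of 17, but in 0 in the authors' value table, in 1 with hur control spots or low-GC scaling, in 3 on the first slide alone, in 4 with the percentile over all probes and in 5 with the replicate block and GC correction, and up to 5 rose (hur control spots). Among them were miR-25-3p (-0.66 ± 0.08) and miR-19b-3p (-0.54 ± 0.08). miR-25-3p did not pass with the percentile over all probes (-0.60), in the authors' value table (-0.04) or with hur control spots (-0.12). miR-19b-3p did not pass in 7 of 29 alternatives, which ranged from -0.76 to 0.19 and turned its direction in 3. The median of this list was -0.37 here and turned to 0.18 in the authors' value table, which is not scaled. miR-21a-5p fell by 0.83 ± 0.09, but did not pass in the authors' value table (-0.22), with hur control spots (-0.29) or with the replicate block and GC correction (-0.11). miR-34a-5p fell by 0.49 ± 0.11. It did not pass in 7 of 29 alternatives (-0.78 to 0.13), among them without Day 2 replicate 2 (-0.38), and turned its direction in 2.

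The largest rises were those of miR-6538 (2.38 ± 0.22, adjusted p = 1e-04), miR-705 (2.21 ± 0.12), miR-3102-5p (2.09 ± 0.17), miR-211-3p (1.94 ± 0.19) and miR-188-5p (1.89 ± 0.19). The sequences of these probes hold 66.7% to 100% GC. Among the 59 tested miRNAs with at least 70% GC, 37 rose and 3 fell at Day 3, against 39 and 84 of the 278 others. Across miRNAs, which are not independent replicates, GC content and the change at Day 3 correlated by 0.50 in Set 1 and 0.52 in Set 2. miR-483-5p, in the mesoderm list, rose by 0.94 ± 0.17 and did not pass on the first slide alone (0.98, adjusted p = 0.111). No let-7 member was called, while normexp called all 5 lower. All 5 lay at the floor on both days, with a change of 0 each, so the main fit could not call them. normexp adds an offset of 50 to every spot before the scaling, so a miRNA without signal moves with the scaling alone. The 75th percentiles of the main scaling were higher at Day 3 (181 and 177) than at Day 2 (130 and 111). A scaling in this direction lowers such miRNAs at Day 3, so these normexp calls are no sign of a fall.

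The lists called by camera were all lower, namely Dlk1-Dio3 (adjusted p = 1.05e-15), miR-290 (adjusted p = 0.00012) and miR-17-92 (adjusted p = 0.00439). With an estimated correlation, Dlk1-Dio3 was called (adjusted p = 0.0268), and the others were not, with adjusted p = 0.455 for miR-290 and adjusted p = 0.641 for miR-17-92. The miR-17-92 call also ended with hur control spots (adjusted p = 0.654) and with the replicate block and GC correction (adjusted p = 0.975). With slide as a block 181 miRNAs were called, and 118 on the first slide alone, and the list medians were -1.40 and -1.35 for miR-290, -1.02 and -0.94 for Dlk1-Dio3, and -0.39 and -0.37 for miR-17-92. The split of 76 higher and 87 lower depends on the scaling, since 13.4% of calls were higher with normexp and 77.8% in the authors' table, against 46.6% here.

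**Figure D2:**
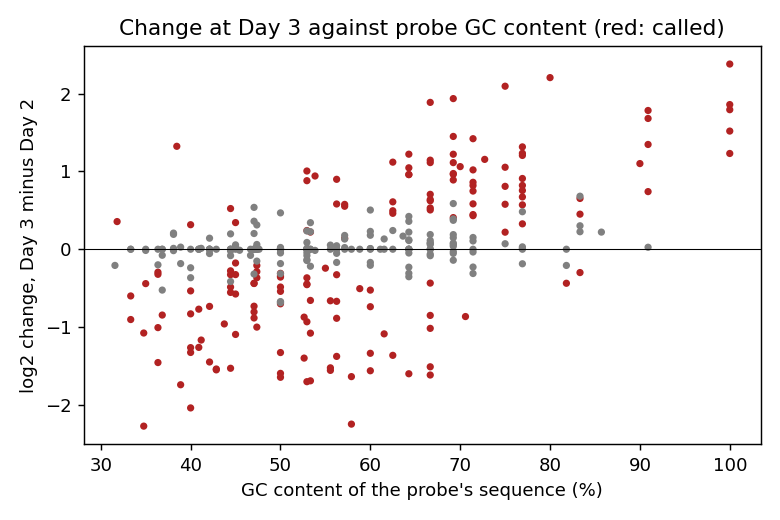
Log2 change from Day 2 to Day 3 (vertical axis) against the GC content of the probe's sequence in percent (horizontal axis), with 1 point for each of the 337 miRNAs and calls in red. Of the 59 miRNAs with at least 70% GC, 37 rose.

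The main comparison sets the end of induction, Day 6, against Day 2. In the miR-290 cluster 11 of 14 members fell. miR-292a-3p went from 10.44 ± 0.14 to 7.02 ± 0.19 (log2 change -3.42 ± 0.19, adjusted p = 4.05e-06), and miR-291a-3p and miR-294-3p each fell by 3.30 ± 0.20. miR-210-3p, which is induced by hypoxia in many cells, was at least 16.6-fold higher, with 7.43 ± 0.10 at Day 6 (adjusted p = 3.81e-07). miR-125a-5p was at least 10.4-fold higher and miR-99b-5p, encoded beside it, at least 6.04-fold.

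Of 337 miRNAs, 195 changed, 122 higher and 73 lower at Day 6. In the miR-290 cluster (chromosome 7, 3218647 to 3220838) miR-295-3p fell by 3.10 ± 0.15 and miR-293-3p by 3.01 ± 0.22, and the arms miR-292a-5p and miR-291a-5p were at least 8.84-fold and 7.71-fold lower. In the miR-302 cluster (chromosome 3, 127248196 to 127248718) 2 of 6 members fell (1 without either array of Day 2 or without Day 6 replicate 2, and 5 with normexp or the total gene signal). They were miR-302a-5p, at least 2.21-fold lower, and miR-367-3p (log2 change -1.23 ± 0.36, adjusted p = 0.0222). miR-302a-3p (-0.89 ± 0.33, adjusted p = 0.0512), miR-302b-3p (-0.74 ± 0.32, adjusted p = 0.0866) and miR-302d-3p (-0.64 ± 0.29, adjusted p = 0.105) did not pass. miR-302a-3p passed in 11 of 29 alternatives, namely with quantile normalization (-0.97), normexp (-0.65), the total gene signal (-1.29), the mean of all probes (-0.85), hur control spots (-1.04), slide as a block (-0.64), without Day 6 replicate 1 (-1.18), and at -0.89 with only miRNAs above background on all arrays, the variance trend, the replicate block or without flat miRNAs. miR-302b-3p passed in 5, from -0.35 with the mean of all probes to -1.08 with the total gene signal, and miR-302d-3p in 2, normexp (-0.50) and the total gene signal (-0.96). miR-367-3p did not pass on the first slide alone (-0.90), nor without either array of Day 2 (-1.06 and -1.40) or Day 6 replicate 2 (-0.90), nor with quantile normalization (-1.18), the authors' value table (-0.92), no filter (adjusted p = 0.11) or low-GC scaling (-0.66).

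Among miR-17-92 members 4 rose and 9 fell (adjusted over the list alone, 4 and 11). None rose with the percentile over all probes or the total gene signal, 1 on the first slide alone and 2 with hur control spots, and 3 fell when scaled on probes of low GC content. All 5 at the chromosome X site fell. miR-363-3p was at least 6.82-fold lower, miR-18b-5p at least 3.26-fold lower, and miR-20b-5p fell by 1.23 ± 0.10. At the chromosome 5 site 3 of 4 rose. The median of the list was -0.34 and turned to 0.08 when scaled on probes of low GC content. Dlk1-Dio3 miRNAs fell in 32 of 36 members (33 adjusted over the list alone, 7 with the floor 4 times higher, and 7 of the 10 above background on all arrays; 1 rose with low-GC scaling), with miR-376b-3p at -2.64 ± 0.09, and miR-154-3p at least 4.11-fold and miR-337-3p at least 2.93-fold lower. The neuronal and endocrine miR-7a-5p was at least 5.42-fold lower. miR-200b-3p fell by 0.96 ± 0.13, but not in the authors' value table (-0.65, adjusted p = 0.14), and miR-141-3p and miR-200c-3p were at least 1.89-fold and 1.85-fold lower.

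Of the let-7 family 3 of 5 members rose (1 with normexp or the floor 4 times higher) and none fell (2 with normexp), with a median of 0.50 that turned to -0.02 with normexp, where let-7a-5p (0.14) did not pass. let-7e-5p was at least 4.76-fold higher, let-7a-5p at least 2.02-fold and let-7f-5p at least 1.42-fold, while let-7g-5p was not well above background on either day. let-7f-5p did not pass in 8 of 28 alternatives, among them without either array of Day 2 (adjusted p = 0.092 and adjusted p = 0.0959) or without Day 6 replicate 2 (0.24), and was -0.02 with normexp. The miR-99, miR-100 and miR-125 list rose in 4 of 5 members (2 with the floor 4 times higher), with miR-125b-5p at least 4.28-fold and miR-125a-3p at least 2.91-fold higher. miR-99b-5p (17967165 to 17967179) and let-7e-5p (17967334 to 17967351) lie side by side on chromosome 17. Other large rises were those of miR-711 (at least 6.91-fold), miR-23a-3p (at least 6.60-fold), miR-7002-5p (at least 5.56-fold), miR-710 (at least 4.81-fold), miR-7036a-5p (2.58 ± 0.24), miR-103-3p (2.27 ± 0.06) and miR-301a-3p (2.26 ± 0.08). miR-21a-5p rose by 0.90 ± 0.09, and miR-34a-5p differed by 0.20 ± 0.11 (adjusted p = 0.169). miR-34a-5p passed when scaled on probes of low GC content (0.77, adjusted p = 8.71e-05), in the authors' value table (0.54), with the mean of all probes (0.24) and with the replicate block and GC correction (0.31).

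Few markers of particular lineages passed the filter. Of 31 endoderm, gut, liver and pancreas miRNAs on the array 2 were tested and both rose, miR-148a-3p by 0.97 ± 0.10 (0.08 and not called with normexp) and miR-744-5p at least 1.55-fold. The miR-744-5p call ended in 8 of 28 alternatives, among them without either array of Day 2 (adjusted p = 0.0513 and adjusted p = 0.0531) or without Day 6 replicate 2 (0.52). miR-375-3p, miR-122-5p, miR-192-5p, miR-9-5p and miR-1a-3p were above background on 0 arrays, and miR-10a-5p on 2 arrays without passing the filter. Of 3 neural members miR-218-5p was at least 3.71-fold higher, miR-212-3p differed by 0.30 ± 0.26 (0.87 and called when scaled on probes of low GC content) and miR-124-3p was below background. miR-483-5p of the mesoderm list passed at 0.50 ± 0.17 (adjusted p = 0.0435), but not in 20 of 29 alternatives, among them each left-out array except Day 2 replicate 1 and Day 6 replicate 1 (0.24 without Day 2 replicate 2). Of the blood and endothelial list miR-126a-3p was at least 1.45-fold higher and miR-142a-3p at least 4.83-fold lower. Of 5 fibroblast and mesenchymal members 2 rose and 1 fell (1 and 3 with normexp or the total gene signal, 1 and 0 on the first slide alone or with the floor 4 times higher), and of the 2 tested Hox miRNAs none was called (1 higher in the authors' value table, 1 lower with normexp). Of 8 members of the Sfmbt2 cluster, miR-669n passed at 0.93 ± 0.30, and no member did when adjusted over the list alone, while 3 were higher in the authors' value table, with the replicate block or with low-GC scaling. The call of miR-669n ended in 12 of 28 alternatives, among them without either array of Day 2 (0.78 and 1.08), either array of Day 3 (adjusted p = 0.0581) or Day 6 replicate 2 (0.65). Its median of 0.38 turned to -0.05 with normexp. The other list counts at Day 6 were the same both ways. Of 3 p53 and stress miRNAs, miR-210-3p and miR-34b-5p (at least 1.13-fold) rose, and the call of miR-34b-5p ended in 6 of 28 alternatives. miR-126a-3p (-0.01) did not pass with normexp either. The floor 4 times higher ended the calls of miR-710 (0.30, adjusted p = 0.375), miR-125b-5p (0.12), miR-142a-3p (-0.27), miR-154-3p (-0.04), and, with a change of 0 each, let-7a-5p, let-7f-5p, miR-302a-5p, miR-18b-5p, miR-337-3p, miR-200b-3p, miR-141-3p, miR-200c-3p, miR-125a-3p, miR-148a-3p, miR-744-5p, miR-218-5p, miR-483-5p, miR-669n, miR-126a-3p and miR-34b-5p.

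By camera the lists called lower were Dlk1-Dio3 (adjusted p = 6.96e-20), miR-290 (adjusted p = 3.44e-07) and miR-17-92 (adjusted p = 0.0177), and the miR-99, miR-100 and miR-125 list was called higher (adjusted p = 0.0221). With an estimated correlation Dlk1-Dio3 was called (adjusted p = 0.0134). The others had adjusted p = 0.203, adjusted p = 0.421 and adjusted p = 0.4 with an estimated correlation, and the miR-17-92 call also ended with quantile normalization (adjusted p = 0.186). With slide as a block 209 miRNAs were called, and 162 on the first slide alone. The list medians were then -2.64 and -2.70 for miR-290, -0.95 and -1.03 for Dlk1-Dio3, -0.34 and -0.36 for miR-17-92, and 2.01 and 1.97 for the miR-99, miR-100 and miR-125 list. The share of higher calls was 62.6% here, 40% with normexp and 78.9% when scaled on probes of low GC content.

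Against the stem cells of Day 0, Day 6 differed in 188 miRNAs, 112 higher and 76 lower. In the miR-290 cluster 12 of 14 members fell (6 of the 6 above background on all arrays), and in the miR-302 cluster 5 of 6 rose. miR-291a-3p fell by 4.00 ± 0.20 (from 10.86 ± 0.04 to 6.86 ± 0.15, adjusted p = 2.96e-06), miR-294-3p by 3.92 ± 0.20, miR-292a-3p by 3.88 ± 0.19, miR-295-3p by 3.84 ± 0.15 and miR-293-3p by 3.79 ± 0.22. miR-302a-3p rose by 2.94 ± 0.33, miR-302d-3p by 2.89 ± 0.29, miR-302b-3p by 2.80 ± 0.32 and miR-367-3p by 2.16 ± 0.36. miR-210-3p rose by 3.71 ± 0.14 and miR-125a-5p by 3.03 ± 0.12.

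Adjusted over the list alone, all list counts in this comparison were the same. Of the let-7 family 4 of 5 members were lower at Day 6 than at Day 0 (2 in the authors' value table, 1 with the floor 4 times higher), with let-7a-5p at -0.88 ± 0.19, let-7f-5p at -1.69 ± 0.15 and let-7g-5p at least 3.41-fold lower, and let-7e-5p was at least 4.76-fold higher. All 5 members of the miR-200 family fell (0 with the floor 4 times higher, 1 with the percentile over all probes, and 3 with hur control spots, in the authors' value table or on the first slide alone), with miR-200b-3p at -0.84 ± 0.13 and miR-200c-3p at least 1.49-fold lower. In the miR-17-92 family 6 rose and 4 fell (3 and 2 with the percentile over all probes; 1 fell on the first slide alone, and 2 with low-GC scaling or the floor 4 times higher), with miR-18a-5p and miR-19a-3p both higher by 1.27. Dlk1-Dio3 miRNAs fell in 17 of 36 and rose in 2. Of them 1 fell with the floor 4 times higher, 24 with the total gene signal, and 6 of the 10 above background on all arrays. The count that rose went from 0 with the percentile over all probes or the total gene signal to 4 with the mean of all probes or low-GC scaling, and was 1 without Day 0 replicate 2 or Day 6 replicate 2. miR-21a-5p rose by 1.78 ± 0.09, miR-218-5p by 1.64 ± 0.04 and miR-483-5p by 1.36 ± 0.17, while miR-34a-5p fell by 0.77 ± 0.11. miR-148a-3p differed by -0.04 ± 0.10 (adjusted p = 0.856), and by -0.57 with a call with the total gene signal. miR-200c-3p did not pass with the percentile over all probes (-0.49), hur control spots (-0.50), no filter (adjusted p = 0.0508), without Day 0 replicate 1 (-0.55) or on the first slide alone (adjusted p = 0.0785), where miR-483-5p (1.21) did not pass either. In the authors' value table let-7a-5p (-0.92), let-7f-5p (-1.55) and miR-200b-3p (-0.71) did not pass. The floor 4 times higher ended the calls of let-7a-5p, let-7g-5p, miR-200b-3p, miR-200c-3p, miR-218-5p and miR-483-5p, with a change of 0 each.

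By camera the lists called lower were miR-290 (adjusted p = 5.67e-09), Dlk1-Dio3 (adjusted p = 0.000174) and miR-200 (adjusted p = 0.0129), and the miR-99, miR-100 and miR-125 list was called higher (adjusted p = 0.0458, and 0.0548 with the replicate block). None was called with an estimated correlation, with adjusted p = 0.217 for the first 3 and adjusted p = 0.395 for the last. The miR-302 list had an adjusted p = 0.0508 and was called with the percentile over all probes (adjusted p = 0.0226), quantile normalization (adjusted p = 0.0466) and hur control spots (adjusted p = 0.0427). With the same 3 scalings the miR-200 call ended (adjusted p = 0.142, adjusted p = 0.0643 and adjusted p = 0.0836). With slide as a block 203 miRNAs were called, and 155 on the first slide alone, with list medians of -3.25 and -3.32 for miR-290, -0.24 and -0.23 for Dlk1-Dio3, and -0.52 and -0.57 for miR-200. The share of higher calls was 59.6% here and 36.3% to 68.4% over the other scalings.

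**Figure D3:**
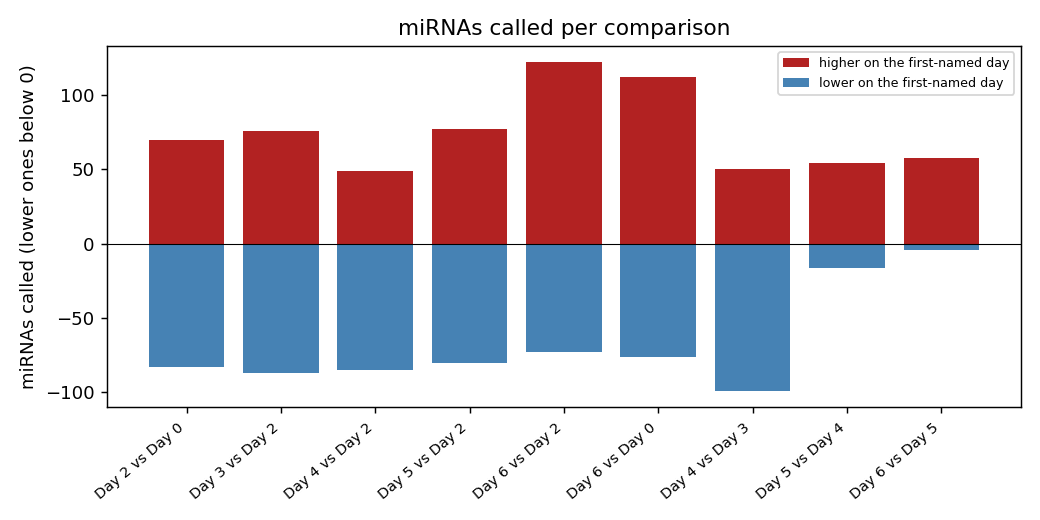
Number of miRNAs called in each comparison (vertical axis), with those higher on the first-named day above 0 and those lower below 0. Day 6 vs Day 2 has 122 higher and 73 lower, and Day 6 vs Day 5 has 58 and 4.

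The days between give the order of these changes. Against Day 2, 134 miRNAs had changed by Day 4 (49 higher, 85 lower) and 157 by Day 5 (77 higher, 80 lower). From Day 3 to Day 4, 149 changed (50 higher, 99 lower), from Day 4 to Day 5, 70 (54 and 16), and from Day 5 to Day 6, 62 (58 and 4). Across miRNAs, GC content and the change from Day 3 to Day 4 correlated by -0.35 in Set 1 and -0.46 in Set 2. This is opposite to the GC trend from Day 2 to Day 3. Whether the end of that trend is a source of the Day 4 changes was not tested. miR-125a-5p and miR-21a-5p rose from Day 3 to Day 4, by 2.11 ± 0.12 and 1.98 ± 0.09. miR-210-3p was still near the floor at Day 4 (3.42 ± 0.06), was at least 7.53-fold higher at Day 5 and rose again to 7.43 at Day 6. On the first slide alone these steps of miR-210-3p did not pass, and the second did not with the percentile over all probes (1.02). Days 3 to 6 have 1 array each on that slide, so its calls here rest on the spread of Days 0 and 2. let-7e-5p was at least 1.57-fold higher at Day 4 than at Day 3 and rose by 1.21 ± 0.07 to Day 5, with both calls ended by the floor 4 times higher (0 each). The share of higher calls was 36.6% for Day 4 vs Day 2 (22.8% to 50.7% over the other scalings), 49.0% for Day 5 vs Day 2 (32.3% to 69.5%), 33.6% for Day 4 vs Day 3 (14.97% to 73.6%), 77.1% for Day 5 vs Day 4 (29.6% to 100%) and 93.5% for Day 6 vs Day 5 (55.8% to 100%). With slide as a block these 5 comparisons gave 153, 172, 182, 104 and 88 calls, and of the calls over all arrays 95, 111, 69, 23 and 27 were also made on the first slide alone. Day 5 vs Day 4 gave 46 calls without Day 4 replicate 1 and 37 without Day 5 replicate 2. Day 6 vs Day 5 gave 40 without either array of Day 0, 32 without Day 5 replicate 1 and 29 without Day 6 replicate 2.

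Over all 6 days the smallest p-values were those of miR-211-5p (adjusted p = 2.38e-10), miR-337-3p (adjusted p = 1.59e-07), and miR-294-5p, miR-218-5p and miR-99b-5p (adjusted p = 1.75e-07 each). With the floor 4 times higher miR-337-3p and miR-218-5p lay at the floor on all arrays. Where both arrays of a group lie at the floor they add a spread of 0 to the fit. Such small p-values can thus reflect the floor rather than close replicates. Of the 260 miRNAs that changed, 77 had their highest mean at Day 6, 59 at Day 3, 56 at Day 0 and 52 at Day 2. Only 7 peaked at Day 4 and 9 at Day 5. These peak days were taken with the main scaling only. For the 157 miRNAs above background on all arrays, other scalings moved the Day 3 vs Day 2 changes by medians of -0.24 to 0.59.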

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

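Of the tests given here, those of the slide and of the GC trend as the whole source were chosen after the result was seen. Control spots were used here only for an alternative scaling by the 4 hur kinds. The other kinds of control spots, such as hur_5 (mean 8.60) and dmr_3 (mean -1.35), were not well above background on every array, except mr_1. The kinds named next were, and carried signal far above blank spots (mean -9.78 over 12 arrays). The mean signal was 10766 for hur_1, 35012 for hur_2, 1288 for hur_4, 6188 for hur_6 and 1043 for mr_1. What these spots measure is not given in the sources used here. The mr_1 signal before scaling was 1640 at Day 0, 819 at Day 2, 681 at Day 3, 751 at Day 4, 1091 at Day 5 and 1279 at Day 6.

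Some miRNAs changed one way from Day 2 to Day 3 and the other way from Day 2 to Day 6, and were also called between Days 3 and 6. There were 18 such miRNAs, of which 16 were lower and then higher, and the first 2 comparisons share the Day 2 arrays. The Day 3 vs Day 2 changes also depend on the scaling. For the 157 miRNAs above background on all arrays they moved by a median of 0.54 log2 with hur control spots. Over all other scalings this ran from -0.24 (total gene signal) to 0.59 (authors' value table). The scaling of the Day 3 arrays as a source of these falls was not tested and stays open. From Day 3 to Day 6 miR-26a-5p went up by 2.49, miR-21a-5p by 1.73, miR-25-3p by 0.92 and miR-22-3p by 0.83. Of these calls, that of miR-25-3p at Day 6 (0.25) ended in 18 of 29 alternatives, among them each left-out array except those of Day 4 and Day 2 replicate 2 (0.17 without Day 2 replicate 1). That of miR-22-3p at Day 3 (-0.29) ended in 16 of 28, among them without either array of Day 0, Day 3 or Day 6 or without Day 2 replicate 2 (-0.18). Those of miR-21a-5p and miR-25-3p at Day 3 each ended in 3 of 29, with values up to -0.11 and -0.04. That of miR-26a-5p at Day 3 ended on the first slide alone (-1.04, adjusted p = 0.0684) and with the floor 4 times higher. That of miR-22-3p at Day 6 ended in 6 of 28, among them the first slide alone (0.60, adjusted p = 0.0546) and the floor 4 times higher.

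miRNAs whose probes hold at least 70% GC were higher at Day 3, with 37 of 59 called higher and a median change of 0.65. A difference between slides is argued against by Set 1, whose Day 2 and Day 3 arrays share a slide and where GC content and change correlated by 0.50 across miRNAs. A linear GC trend as the whole source of the Day 3 changes was tested by its removal. With the replicate block the removal gave 138 calls, and 114 of the 167 calls without it were made again in the same direction. The share of 68.3% lies within its standard error (3.6%) of the bound set for excluding the trend, so the test decides nothing. Values at the floor were also kept there, so calls against the floor can outlast the removal whatever their source. The trend stays open as the whole source or a part of it. Among the GC-rich miRNAs the removal took the calls higher from 38 to 19 and the median from 0.65 to 0.07, which it brings about by itself and so decides nothing. A GC-dependent signal on the Day 3 arrays stays open too. The brighter GC-rich miRNAs moved by 4.61 times the median of the dimmer ones (1.04 against 0.22), which decides nothing because 35.3% of the dimmer values lay at the floor. A biological rise of these miRNAs was not tested and stays open too.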

How the results depend on the processing

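Tests on the first slide alone, with hur control spots, low-GC probes, GC correction or without flat miRNAs were chosen after the data were seen. Among the named calls, miR-19b-3p at Day 3 vs Day 2 turned to 0.067 in the values of the authors, to 0.0038 with hur control spots and to 0.19 with the replicate block and GC correction, and miR-34a-5p to 0.13 and 0.053 with the first 2 of these. At Day 6 vs Day 2 normexp turned let-7f-5p (-0.023), miR-126a-3p (-0.0073), miR-34b-5p (-0.044) and miR-22-3p (-0.041), and miR-25-3p turned with the percentile over all probes (-0.011) and the total gene signal (-0.12). None of these turned values was called. normexp also called let-7g-5p (-0.23) and miR-124-3p (-0.30) lower at Day 6 than at Day 2. Neither was well above background on these days, where the offset of 50 and the scaling move normexp values by themselves. Among all calls of Day 3 vs Day 2, 12 were called the other way with normexp, 3 with hur control spots and 1 in the values of the authors, and in the other comparisons at most 2 under any scaling. The replicate block gave 166 calls for Day 2 vs Day 0, 167 for Day 3 vs Day 2, 214 for Day 6 vs Day 2 and 204 for Day 6 vs Day 0. Among the named results it changed only the calls of miR-302a-3p and miR-483-5p (adjusted p = 0.0541) at Day 6 vs Day 2, of miR-22-3p (adjusted p = 0.0511) at Day 3 vs Day 2 and of the miR-99, miR-100 and miR-125 list at Day 6 vs Day 0. Counts that moved by more than 1.5 times follow, and the cause was not tested unless given. The percentile over all probes gave 99 for Day 2 vs Day 0, 74 for Day 4 vs Day 3, 6 for Day 5 vs Day 4 and 13 for Day 6 vs Day 5. normexp gave 268 for Day 3 vs Day 2 and 29 for Day 6 vs Day 5. Of the 268 calls 232 were lower, the direction in which the offset and the scaling move miRNAs without signal at Day 3. The total gene signal gave 36 for Day 6 vs Day 5, and the values of the authors gave 36 for Day 5 vs Day 4 and 31 for Day 6 vs Day 5. No filter gave 32 and 29 for these. The first slide alone, with fewer arrays, gave 84 for Day 4 vs Day 3 and 32 for Day 5 vs Day 4. With only the 157 miRNAs above background on all arrays, fewer were tested, and Days 2 vs 0, 3 vs 2, 4 vs 2, 5 vs 2, 6 vs 2, 6 vs 0, 4 vs 3, 5 vs 4, 6 vs 5 and any change gave 82, 95, 63, 72, 86, 92, 99, 42, 30 and 132. A floor 4 times higher, which removes dim differences, gave 72, 72, 37, 48, 73, 75, 50, 13, 19 and 110 in the same order. Lists called numbered 5, 3, 4 and 4 for Day 2 vs Day 0, Day 3 vs Day 2, Day 6 vs Day 2 and Day 6 vs Day 0, against 1, 1, 1 and 0 with an estimated correlation and 8, 5, 10 and 10 with fry, which does not compare a list with other miRNAs. Leaving out each array, where the lone array is taken to vary like the other groups, gave 135 to 157, 145 to 165, 112 to 133, 131 to 156, 169 to 203, 155 to 193, 124 to 152, 37 to 64, 29 to 82 and 244 to 266 in the order above. Day 5 vs Day 4 gave 46 without Day 4 replicate 1 and 37 without Day 5 replicate 2. Day 6 vs Day 5 gave 40 without either array of Day 0, 32 without Day 5 replicate 1 and 29 without Day 6 replicate 2. Signal over background limits dim miRNAs, since 126 of 337 lay at the floor on 6 or more arrays.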

Other observations

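Of the tests given here, the grouping of miRNAs named in the first paragraph and the tests of the shared arrays, of the slide and of a difference from the start were chosen after the results were seen. A group of miRNAs fell in basal medium and was higher again at Day 6. There were 51 miRNAs called lower at Day 2 than at Day 0 and higher at Day 6 than at Day 2. It holds all 5 tested members of the miR-30 family, which is found in many differentiated tissues. miR-30a-5p fell by 1.47 and then rose by 1.93, and miR-30b-5p fell by 1.30 and rose by 1.37. miR-24-3p fell by 2.07 and rose by 2.12, and miR-27a-3p, from the same cluster, fell by 0.97 and rose by 2.23. miR-103-3p fell by 1.68 and rose by 2.27, and its relative miR-107-3p fell by 1.75 and rose by 2.08. With the floor 4 times higher the falls of miR-30a-5p, miR-30b-5p and miR-27a-3p and the rises of both miR-30 members were not called.

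Both comparisons share the 2 Day 2 arrays. Independent lists would overlap by 30.0 miRNAs against the observed 51, and the opposite pattern, higher at Day 2 and lower at Day 6, held 44 against 15.2. Noise of the shared arrays as the source of the overlap is argued against by a fit in which each comparison had a Day 2 array of its own. The overlaps were then 39 and 43 miRNAs, all among the 51, against 23.5 and 22.2 for independent lists. The scaling of the Day 2 arrays as the source of the group was tested with hur control spots, with which 41 of the 51 were called both ways. The medians of the 51 went from -1.13 to -1.03 for the falls and from 0.97 to 0.83 for the rises. This met the bound set for arguing against the scaling, but what these spots measure is not known. Their signal before scaling was itself lower at Day 2, with 11376 at Day 0, 9211 at Day 2 and 12273 at Day 6 for hur_1. The scaling as the source thus stays open, though both medians of the 51 kept their direction under every scaling tried. Fewer were called both ways with the percentile over all probes (24, with medians of -1.06 and 0.72) and with normexp (29, with -0.27 and 0.30), and 38 to 50 with the other scalings. Other errors common to both Day 2 arrays were not tested. An effect of the medium or of the inducers was not tested either, and stays open.

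Differences between Set 1 and Set 2 were shared by Days 3 to 6, with correlations of 0.515 to 0.785 across miRNAs. A difference between the experiments from the start as the whole source is argued against by the median correlation of 0.0846 between Days 0 and 2 and the later days. The values were -0.277 to 0.152 for Day 0 and 0.0481 to 0.308 for Day 2. As a part of the source it stays open, since a slide difference at Days 3 to 6 could lower these correlations. A slide difference stays open. The median absolute set difference at Days 3 to 6, where the sets lie on different slides, was 1.58 times that of Days 0 and 2, but 3.02 times that of Day 0 and 1.07 times that of Day 2. A different pace of differentiation may also contribute, and stays open. The set difference at Days 4 and 5 correlated by -0.371 with the change from Day 3 to Day 6. On these days the sets lie on different slides, so this value cannot tell pace from a slide difference.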
